A study of Rattus norvegicus with 36 samples.

How the data were processed

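RNA was measured in primary alveolar macrophages of male F344 rats kept in culture, in 36 samples that the labels place in 12 groups of 3 biological replicates: control, non-overload and overload for each of 4 particles. Per the labels' protocols, the cells were kept for 5 days in DMEM with 10% fetal bovine serum and 1% antibiotic-antimycotic at 37 °C and 5% CO2, and exposed for 4 days. RNA was isolated with TriPure reagent, and libraries were made from 150 ng of total RNA with the KAPA RNA HyperPrep kit with RiboErase, which depletes ribosomal RNA, per the labels' protocols. The authors deposited 1 table of expected counts for 23487 genes by gene name, in which 30.5% of the values had decimals. FastQC, MultiQC, Salmon and the Rnor_6.0 build are named in the submitters' processing notes, with neither versions nor settings, which are not given in the sources used here. Of the 36 columns, 24 carried a sample's description label, and the 12 control columns carried it with CT in place of CTL. Each was matched to its sample by it, and no column was left unused.

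The expected counts were rounded to whole numbers, and no row lacked a gene name. Of the names, 16711 were symbols in RefSeq's annotation of the GRCr8 assembly, 88 were after a full stop was read as a hyphen, and 6688 were neither. The builds differ, so that annotation was used for names only, and no coordinates or sequences are given. Counts were summed per gene by the authors, and reads of near-identical copies, such as the MHC class II genes, metallothioneins and globins, can be split between them, so their single values are uncertain. Overlapping and antisense genes are uncertain in the same way, since the use of strand in counting is not given in the sources used here.

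Counts were tested with edgeR 4.0.16 in R 4.3.3: scaling by trimmed mean of M-values (TMM), filterByExpr with a minimum count of 10 and a minimum total of 15, and a quasi-likelihood fit of all 36 libraries with 1 coefficient per group and 24 residual degrees of freedom. This left 14606 genes, and 3287 genes had no count in any library. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Tested were overload against control, non-overload against control and overload against non-overload of each particle, the 6 differences between overload responses, and the mean of the 4 overload responses. Errors of log2 fold changes are standard errors (SE), and levels are CPM as mean ± SD over 3 libraries.

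The 34 gene lists were fixed with the comparisons before the data were examined, and 33 had the minimum of 3 measured members; the mast cell and eosinophil list did not. Each list was tested with the directional fry test of limma 3.58.1, adjusted over the lists within a comparison, and again with limma's camera with an estimated correlation between genes. Fry tests whether a list's genes move one way on balance and does not compare them with other genes. Camera asks whether they move more than the other genes, and its p-values are those given as with an estimated correlation. A list can therefore pass fry and fail camera because many other genes moved as well. Counts of list members are over all genes tested, and also adjusted over the list alone. Lists can share genes: Il1b is in the cytokine and inflammasome lists, Nqo1 in the AhR and NRF2 lists, and Mmp8 in the remodelling and neutrophil lists. Many markers of other cell types can also be expressed by macrophages.

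The rule for naming genes was set before the data were examined. It took, among called genes with a symbol, a mean of at least 1 CPM in the higher group and no overlap between the groups' libraries, the 8 largest changes each way for overload against control and the mean response, where no overlap was asked within each particle, and 4 each way for the other comparisons within a particle. With 3 libraries against 3, chance gives no overlap in 10% of cases. It took 3 each way for each difference, without the overlap condition, and the 4 members of each list with the smallest p in the mean response. Where 5 or fewer members of a list were called, any of them could be named. Placeholder names were left out.

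Total counts were 26.1 to 43.2 M per library. The 36 pairs of replicates within groups differed by a chi-square per degree of freedom of 3.71 to 35.4, so none was counted as 1 library sequenced again. The common biological coefficient of variation was 0.103. The median log2 fold change of all genes lay within 0.02 of 0 in the comparisons with TMM, and within 0.022 with DESeq2's size factors. The pipeline was tested on simulated counts: for G3-1 overload against control, 14606 genes with 67, 67 and 66 changed by 1.5-, 2- and 4-fold, it recovered 82.1%, 94% and 98.5% of them and called 9 of 14306 others. For the difference Printex90 minus G3-1 it recovered 58.2%, 88.1% and 97% and called 15 of 14306 others. The list test recovered 4 of 4 lists changed by 1.2-fold and called 0 of 16 unchanged lists in the simulated G3-1 comparison. Simulated counts were drawn for each gene separately, without correlation between genes and without differences in cell types between libraries. The shares recovered and falsely called therefore need not hold in the real data.

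The fibroblast level of a library is the mean log2 CPM, with a pseudocount of 0.5, of 10 markers from the fixed lists. The level of 3 that sets 8 libraries apart was chosen after seeing the data. The labels give only replicate numbers, and the main fit did not treat these as pairs in any comparison. Only in Printex90 non-overload against control did the deviations from the group means correlate over 0.1 in all 3 pairs of the same number. There they correlated at 0.21, 0.43 and 0.43. Both libraries numbered 2 had a fibroblast level above 3, which can also give such correlations, so the pairing is not certain. Principal components were taken from log2 CPM with a prior count of 2. Alternatives planned beforehand were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a fit of only the particles compared, the replicate number as a block, camera, and leaving out each library in turn. The fibroblast level as a covariate and the fit without the 8 libraries were added after seeing the data. Mice and humans, named in the series title, were not analysed here.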

Results

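Gene expression was measured by RNA sequencing in primary alveolar macrophages of male F344 rats, the phagocytes that take up inhaled particles in the air spaces of the lung. The cells were exposed in culture for 4 days to Printex90, a carbon black, or to G1-1, G3-1 or Bayertitan, which are titanium dioxide particles. Each of the 4 particles had its own control, non-overload and overload cultures, with 3 biological replicates per group, which gave 12 groups and 36 libraries. The series asks how alveolar macrophages respond to particle overload, and the amounts of particle behind each condition are not given in the sources used here. Total counts ran from 26.1 to 43.2 M per library, and 14606 genes were tested. The labels do not say whether the replicates came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

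Markers of other cell types were also present and differed between libraries. Col3a1, a collagen gene of fibroblasts, lay between 13.6 and 109 CPM (counts scaled to library size) in 8 libraries and at no more than 2.87 CPM in the other 28. The 8 libraries were replicate 2 of G1-1 overload, of Printex90 control and of Printex90 non-overload, replicates 1 and 2 of G3-1 control and of G3-1 overload, and replicate 1 of Bayertitan non-overload. Collagen genes led the first principal component, which carried 24% of the variance. Epithelial transcripts were seen in all 36 libraries, with Krt7, a keratin, between 485 and 1060 CPM. The mean log2 CPM of the epithelial markers was 3.86 ± 0.179 (SD, n = 3) in G1-1 control and 3.51 ± 0.186 in G1-1 overload. It was 3.67 ± 0.35 in Printex90 control and 3.22 ± 0.0473 in Printex90 overload.

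**Figure D1:**
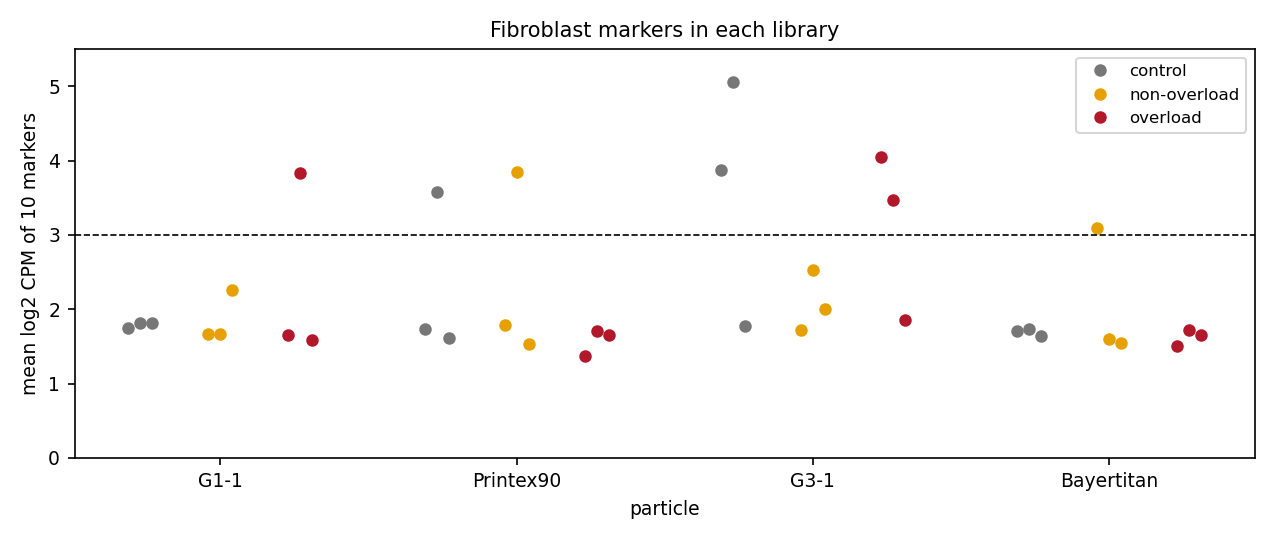
Mean log2 CPM of 10 fibroblast markers in each library, with 1 point per library, by particle and condition. The 8 libraries above the line at 3 include controls of Printex90 and G3-1 as well as exposed cultures.

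The comparison of G1-1 overload with its control asked which genes overload with this titanium dioxide changed. By limma's fry test the lists of hypoxia and glycolysis, lysosomal and tissue remodelling genes rose, and those of MHC class II, heat shock and interferon-stimulated genes fell. By limma's camera with an estimated correlation between genes none of these 6 passed (adjusted p = 0.374, 0.637, 0.284, 0.284, 0.0756 and 0.686). Camera compares a list with the other genes, which fry does not, so the 2 tests ask different questions wherever both are given. Nos2, the inducible nitric oxide synthase, rose from 0.914 ± 0.543 to 6.14 ± 4.08 CPM (SD, n = 3), a log2 fold change of 2.72 with SE 0.58 and adjusted p = 0.000609 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Scd, a stearoyl-CoA desaturase, rose by 1.61 on the log2 scale, and Apln, which encodes the peptide apelin, by 1.79. Tlr1, a receptor for bacterial lipopeptides, fell from 1.53 ± 0.175 to 0.209 ± 0.184 CPM (log2 -2.87, SE 0.38, adjusted p = 9.69e-07), and Fcrl2, an Fc receptor-like gene, from 15.2 ± 1.44 to 3.26 ± 0.469 CPM (log2 -2.22, SE 0.2, adjusted p = 9.93e-10). In total 4105 genes differed, 1997 higher and 2108 lower, of which 65 and 104 changed by 2-fold or more. Other leading increases were Sost at 1.70, Rgs9 at 1.61, Sbk1 at 1.61 and Cited4 at 1.60, and other leading decreases were Krt15 at -2.16, Akap5 at -2.07, Tnnt2 at -1.69, Hmgn5 at -1.68, Il21r at -1.64 and Tp63 at -1.63. The keratin gene Krt15 and Tp63 mark basal epithelial cells, and these decreases accompanied the lower epithelial level given above. Snai1 had a fitted log2 fold change of 3.63, but its level came from replicate 2 of G1-1 overload, a library with high Col3a1, where it reached 6.07 CPM, and it was 1.09 and no longer called without that library. It also lost its call without control replicate 1 (3.68), 2 (3.33) or 3 (3.94). Akap5 was at -0.90 without control replicate 2, and it lost its call there and without overload replicate 1 (-2.02) or 3 (-1.88), as did Hmgn5 without overload replicate 1 (-1.50) or 3 (-1.48) and Tnnt2 without overload replicate 1 (-1.34).

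Among the gene lists in G1-1 overload, 19 of the 25 genes of hypoxia and glycolysis rose and none fell (19 adjusted over the list alone, median log2 fold change 0.40). The list passed limma's fry test with adjusted p = 0.000193, and had adjusted p = 0.374 with an estimated correlation. The kinase genes Pfkfb3 and Pdk1, which steer glucose into glycolysis, rose by 0.85 and 0.66, the glycolytic enzyme gene Gpi by 0.44, and Bnip3 by 0.89. Of 41 lysosomal genes, 23 rose and 2 fell (25 and 3 adjusted over the list alone), with a fry adjusted p = 0.00851 and adjusted p = 0.637 with an estimated correlation. Ctsd, a lysosomal protease, rose by 0.58, Gaa by 0.59 and Npc1, which exports cholesterol from lysosomes, by 0.51. Of 32 remodelling genes 11 rose and 2 fell, the same numbers adjusted over the list alone, with a fry adjusted p = 2.77e-05 and adjusted p = 0.284 with an estimated correlation. The collagenase gene Mmp8 rose by 1.42 and Mmp14 by 0.41, and Areg fell by 0.76. Mmp8 is also a neutrophil marker, and 2 of 8 markers of that cell type rose (Mmp8 and Cxcr1, also 2 adjusted over the list alone, fry adjusted p = 1.13e-05 and adjusted p = 0.284 with an estimated correlation).

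Genes of MHC class II moved the other way in G1-1 overload. Of 14 genes of MHC class II and co-stimulation 9 fell and none rose (10 down and 1 up adjusted over the list alone), with a median log2 fold change of -0.51 and a fry adjusted p = 1.13e-05. The list had adjusted p = 0.284 with an estimated correlation. Cd74, the invariant chain, fell by 1.01 and RT1-Db1 by 0.94, and Ciita, the regulator of the class, chosen after its value was seen, had a log2 fold change of -0.62. Of 15 heat shock genes 8 fell and 3 rose (9 and 4 adjusted over the list alone), with a fry adjusted p = 1.34e-09 and adjusted p = 0.0756 with an estimated correlation. The chaperone genes Hsp90ab1 at -0.51, Hsph1 at -0.46 and Dnaja1 at -0.37 were among those lower. Of 29 interferon-stimulated genes 11 fell and none rose (13 and 0 adjusted over the list alone), with Cxcl10 at -1.54 and Gbp5 at -0.87, a fry adjusted p = 0.0178 and adjusted p = 0.686 with an estimated correlation. Cytokine genes went both ways: Il1b had -1.38 and Osm 0.43, with 5 up and 1 down of 25 (the same adjusted over the list alone), and a fry adjusted p = 0.0164 upward with adjusted p = 0.637 with an estimated correlation. The inflammasome list, which also holds Il1b, fell with 5 down and 1 up of 14 (8 and 1 adjusted over the list alone, fry adjusted p = 0.000226 and adjusted p = 0.627 with an estimated correlation), and Nlrc4 was lower by a log2 fold change of -0.58. The metallothionein list rose (fry adjusted p = 0.00449 and adjusted p = 0.637 with an estimated correlation), with Mt1 at 0.83.

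Further lists passed the fry test in G1-1 overload. Alveolar macrophage identity genes rose (fry adjusted p = 0.00767 and adjusted p = 0.637 with an estimated correlation), with the sialic acid receptor Siglec1 at 0.60 and the arginine transporter Slc7a2 at 0.73. Monocyte markers fell (fry adjusted p = 0.00825 and adjusted p = 0.686 with an estimated correlation), with Cx3cr1, the fractalkine receptor, at -2.18 and Csf1r at -0.34. Epithelial markers fell (median -0.46, fry adjusted p = 0.0211 and adjusted p = 0.686 with an estimated correlation). Cholesterol biosynthesis rose by fry (adjusted p = 0.0161, and adjusted p = 0.637 with an estimated correlation). For liver X receptor (LXR) targets the test was upward (fry adjusted p = 0.0171 and adjusted p = 0.637 with an estimated correlation) and the median 0.11, while the mean was -0.06. For dendritic cell markers the test was upward (fry adjusted p = 0.0264 and adjusted p = 0.686 with an estimated correlation), while the median was -0.02 and the mean -0.12. The remaining lists past the fry threshold were base excision repair downward, B lymphocyte markers upward and targets of the aryl hydrocarbon receptor (AhR) downward, with adjusted p = 0.0164, 0.016 and 0.0211, and none of the 19 lists passed with an estimated correlation, where these had adjusted p = 0.686, 0.637 and 0.686. The share of counts from ribosomal protein genes was 1.93 ± 0.0924% (SD, n = 3) in G1-1 control and 1.44 ± 0.0351% in G1-1 overload.

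At the non-overload condition of G1-1 fewer genes differed from control. Apln rose from 0.802 ± 0.221 to 3.01 ± 0.108 CPM (log2 1.89, SE 0.41, adjusted p = 0.0259 by edgeR), Sost by 0.89 and Htr2b, a serotonin receptor, by 0.69. The lipoprotein receptor gene Lrp8 had a log2 fold change of -0.40, Osbpl3 -0.33, Rrp12 -0.29 and the chaperone gene Hsph1 -0.21. The hypoxia and glycolysis list rose with 6 of 25 genes up (18 up and 1 down adjusted over the list alone, fry adjusted p = 0.00949 and adjusted p = 0.0411 with an estimated correlation). Alternative activation genes rose as a list with none past the threshold singly over all genes and 3 up adjusted over the list alone (fry adjusted p = 0.000105 and adjusted p = 0.00292 with an estimated correlation), and heat shock genes fell with 1 gene down (6 adjusted over the list alone, fry adjusted p = 0.000105 and adjusted p = 0.00381 with an estimated correlation). MHC class II genes (fry adjusted p = 0.0393, and adjusted p = 0.115 with an estimated correlation) and neutrophil markers (fry adjusted p = 0.00949, and adjusted p = 0.0639 with an estimated correlation) also rose by fry. Altogether 67 genes passed, 60 higher and 7 lower. The 7 named genes kept their sign and lost their call without non-overload replicate 2, where Apln was at 1.89, and Apln, Sost, Osbpl3 and Rrp12 lost it without any 1 of the 6 libraries. The count was 0 when the fit held the libraries of G1-1 alone. It was 17, 15 and 15 without control replicates 1, 2 and 3, and 25, 3 and 36 without non-overload replicates 1, 2 and 3. DESeq2 called 157 genes, and edgeR 201 with the fibroblast marker level in the fit.

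Between overload and non-overload of G1-1, 3315 genes differed, 1510 higher and 1805 lower in overload. Scd rose by 1.27, Cited4 by 1.26 and Igf2bp1 by 1.17, and Tlr1 (log2 -2.53, SE 0.38, adjusted p = 1.1e-05 by edgeR), Fcrl2 at -2.40, Cadm3 at -1.97 and Oas2, an interferon-induced gene, at -1.67 were lower. MHC class II genes fell with 10 of 14 down (11 adjusted over the list alone, median -0.83, fry adjusted p = 6.07e-08, and adjusted p = 0.0396 with an estimated correlation), the opposite sign to the list's test between non-overload and control. The list of interferon-stimulated genes fell by fry (adjusted p = 0.0208, and adjusted p = 0.806 with an estimated correlation), with 11 of 29 genes down and 17 adjusted over the list alone. Heat shock genes fell again (fry adjusted p = 0.000105, and adjusted p = 0.532 with an estimated correlation). Alternative activation genes fell between these conditions (fry adjusted p = 0.000102, and adjusted p = 0.532 with an estimated correlation), with 4 down and 1 up. For neutrophil markers fry pointed upward (adjusted p = 0.0208, and adjusted p = 0.781 with an estimated correlation) with a mean of 0.02, while the median was -0.13.

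**Figure D2:**
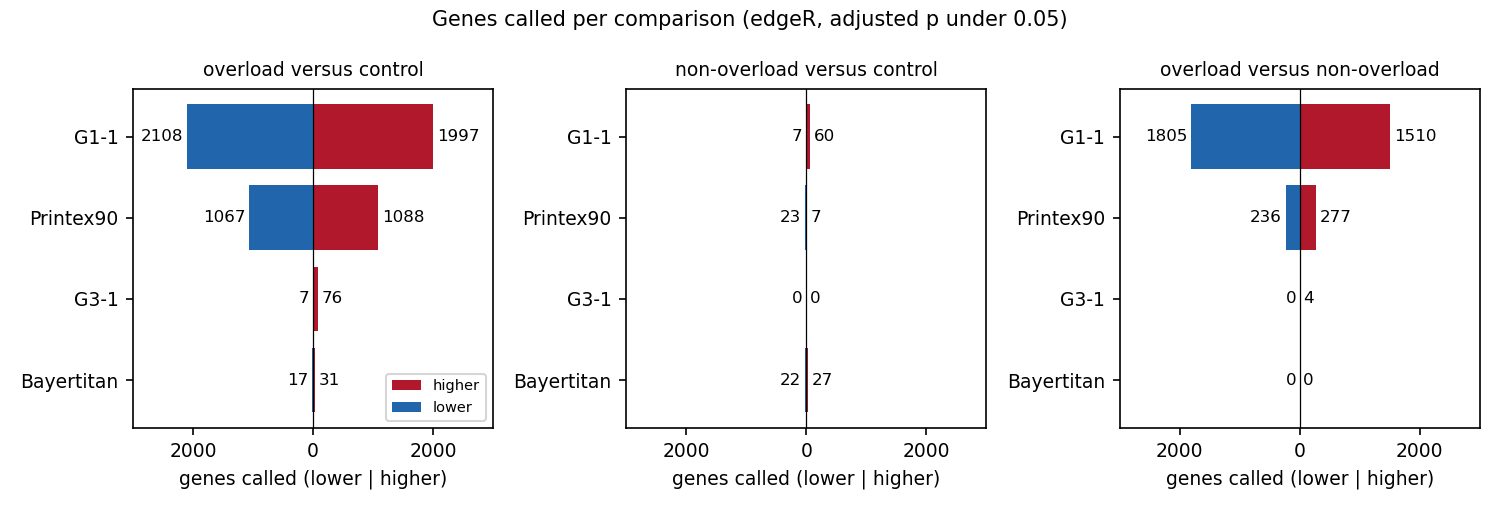
Number of genes called higher (right of 0) and lower (left of 0) in each comparison of conditions within a particle by edgeR's quasi-likelihood test. The counts run from 4105 genes for G1-1 overload against control to 0 for G3-1 non-overload against control and for Bayertitan overload against non-overload.

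Printex90 overload against its control asked the same of carbon black. Targets of AhR, a ligand-activated receptor that induces enzymes for aromatic hydrocarbons, fell furthest, MHC class II, cytokine and alternative activation genes also fell, and cholesterol biosynthesis genes rose. Hypoxia and glycolysis genes rose by fry alone, with adjusted p = 0.0764 with an estimated correlation. Cyp1b1 fell from 75.1 ± 17.8 to 1.65 ± 2.52 CPM (SD, n = 3), with a log2 fold change of -5.49, SE 0.58 and adjusted p = 1.17e-07 in edgeR's quasi-likelihood test. Cyp1a1 fell from 2.27 ± 1.02 to 0.0493 ± 0.0853 CPM (log2 -5.40, SE 0.67, adjusted p = 2.08e-06) and Ahrr, the AhR repressor, had -3.22 (SE 0.25, adjusted p = 2.77e-10). Overload replicate 2 had 4.55 CPM of Cyp1b1, the most of the 3, and without it Cyp1b1 was at -8.65 and Cyp1a1 at -9.26, both still called. Stab1, a scavenger receptor of macrophages, fell from 62.2 ± 5.82 to 8.36 ± 2.57 CPM (log2 -2.91, SE 0.19, adjusted p = 6.77e-12). Mmp8 rose from 12.9 ± 1.12 to 47.2 ± 2.49 CPM (log2 1.88, SE 0.11, adjusted p = 7.69e-13). In all 2155 genes differed, 1088 higher and 1067 lower, of which 28 rose and 212 fell by 2-fold or more. Igf2bp1, an RNA-binding protein gene, rose by 2.39, the ion channel gene Trpm8 by 2.0, Aoc1 by 1.47, Sost by 1.36, G0s2 by 1.32, Tspan10 by 1.31 and the aldolase gene Aldoc by 1.26. Ptges, the prostaglandin E synthase, had a log2 fold change of -4.72, Cadm3 -3.02 and the basal epithelial keratin gene Krt5 -3.20. Trappc2b had no count in any overload library and 1.6 ± 0.753 CPM in control. The count of genes was 1081, 1168 and 2861 without control replicates 1, 2 and 3, 997 without overload replicate 1, and 1373 when the fit held the Printex90 libraries alone.

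AhR targets fell in 6 of 9 cases and rose in none with Printex90 overload (7 adjusted over the list alone, median -1.16, fry adjusted p = 3.86e-12, and adjusted p = 1.03e-05 with an estimated correlation). Nqo1, an AhR target and an antioxidant gene, had -1.16. Of the MHC class II list 9 of 14 fell and none rose (10 adjusted over the list alone, median -0.87, fry adjusted p = 7.52e-11, and adjusted p = 2.36e-05 with an estimated correlation), with RT1-Bb at -1.87, RT1-Db1 at -1.70 and Cd74 at -1.62. Cytokine genes fell, 9 down and 1 up of 25 (12 and 1 adjusted over the list alone, fry adjusted p = 1.67e-05, and adjusted p = 0.0361 with an estimated correlation). Il1b had -1.13 and Il18, the member that rose, 0.29. The neutrophil-attracting chemokine gene Cxcl3, chosen after its value was seen, had -0.97. The alternative activation list fell with 5 of 17 down (9 down and 3 up adjusted over the list alone, fry adjusted p = 8.87e-07, and adjusted p = 0.0179 with an estimated correlation). Cholesterol biosynthesis rose with 12 of 25 genes up (15 up and 1 down adjusted over the list alone, fry adjusted p = 4.3e-06, and adjusted p = 0.0244 with an estimated correlation), including Sc5d at 0.52 and Insig1 at 0.37. Neutrophil markers rose through Mmp8 and Cxcr1, 2 of 8 (the same number adjusted over the list alone, fry adjusted p = 2.9e-06, and adjusted p = 0.0229 with an estimated correlation).

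The other lists past the fry threshold with Printex90 overload did not pass with an estimated correlation. Hypoxia and glycolysis rose with 17 of 25 genes up (21 up and 1 down adjusted over the list alone, fry adjusted p = 2e-04, and adjusted p = 0.0764 with an estimated correlation), with Pdk1 at 0.65 and Pfkfb3 at 0.66. Lysosomal genes rose with 19 of 41 up and 1 down (fry adjusted p = 0.024, and adjusted p = 0.425 with an estimated correlation), and autophagy genes with 10 up of 25 and 0 down (fry adjusted p = 0.00673, and adjusted p = 0.343 with an estimated correlation), among them Optn at 0.55 and Rragd at 0.56. Metallothionein and metal transport genes rose (fry adjusted p = 0.00071, and adjusted p = 0.127 with an estimated correlation), with Mt1 at 0.68. Epithelial markers fell with 3 of 16 down (7 adjusted over the list alone, median -0.48, fry adjusted p = 0.024, and adjusted p = 0.425 with an estimated correlation), with the club cell gene Scgb1a1 at -2.30 and Hopx at -0.39. Monocyte markers fell, Cx3cr1 by 3.26 and Csf1r by 0.44, while F13a1 rose by 0.69 (fry adjusted p = 0.00414, and adjusted p = 0.343 with an estimated correlation). The inflammasome, NF-kB feedback and p53 target lists fell by fry (adjusted p = 0.0197, 0.0377, and 0.0136, and adjusted p = 0.425, 0.497 and 0.425 with an estimated correlation), as did the 3 erythrocyte markers through Hba-a2 at -0.68 (fry adjusted p = 0.011, and adjusted p = 0.425 with an estimated correlation). LXR targets had an upward test (fry adjusted p = 0.0489, and adjusted p = 0.448 with an estimated correlation) and a median of 0.09 beside a mean of -0.14.

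At the non-overload condition of Printex90, AhR targets and MHC class II genes were already lower than in control. Cyp1a1 fell from 2.27 ± 1.02 to 0.212 ± 0.039 CPM (log2 -3.38, SE 0.53, adjusted p = 0.00163 by edgeR), Ahrr had -1.35, Nqo1 -0.72, the growth factor gene Nrg1 -0.95 and Stab1 -0.93. Increases included Mcf2l at 0.57, Mmp8 at 0.56, Prune2 at 0.55 and Ak4, a hypoxia-induced adenylate kinase, at 0.40. AhR targets fell with 3 of 9 down (5 adjusted over the list alone, fry adjusted p = 9.6e-07, and adjusted p = 3.5e-06 with an estimated correlation), and MHC class II with 5 of 14 down (6 down and 1 up adjusted over the list alone, fry adjusted p = 0.00974, and adjusted p = 0.017 with an estimated correlation). Hypoxia and glycolysis genes rose with 1 gene up, P4ha1 at 0.31, and 17 adjusted over the list alone (fry adjusted p = 0.0305, and adjusted p = 0.0321 with an estimated correlation). The count of genes was 30, 7 higher and 23 lower. Without non-overload replicate 1, Stab1 (-0.89), Nrg1 (-0.90), Mcf2l, Mmp8, Prune2 and Ak4 kept their sign and lost their call, while Cyp1a1 and Ahrr kept theirs whichever library was left out. Stab1 (-0.92) was also lost without control replicate 2, and the other 5 without control replicates 1 and 2 and in some cases more. The count was 11 without the 8 libraries of high Col3a1, 5 in the fit of the Printex90 libraries alone, 12 and 9 without control replicates 1 and 2, and 10, 19 and 14 without non-overload replicates 1, 2 and 3. DESeq2 called 58 genes, as did edgeR with the fibroblast marker level in the fit. With the replicate number as a block, Mcf2l (0.57) lost its call and the cytokine list fell by fry (adjusted p = 0.00996, against 0.0505 without the block).

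Between overload and non-overload of Printex90, 513 genes differed, 277 higher and 236 lower in overload. Ptges had a log2 fold change of -3.96, Cyp1b1 -3.66, Krt5 -2.19 and Hs6st2 -2.07, and Igf2bp1 rose by 2.29, Mmp8 by 1.31 and Pcp4 by 1.00. MHC class II genes fell further, 8 of 14 (the same number adjusted over the list alone, fry adjusted p = 1.03e-07, and adjusted p = 9.7e-05 with an estimated correlation), as did AhR targets, 3 of 9 (4 adjusted over the list alone, fry adjusted p = 3.94e-06, and adjusted p = 0.00211 with an estimated correlation). Cholesterol biosynthesis rose, 11 of 25 (17 adjusted over the list alone, fry adjusted p = 5.48e-06, and adjusted p = 0.00288 with an estimated correlation). Alternative activation genes (fry adjusted p = 4.35e-05, and adjusted p = 0.00891 with an estimated correlation) and monocyte markers (fry adjusted p = 0.000261, and adjusted p = 0.0195 with an estimated correlation) also fell. Without non-overload replicate 2, a library of high Col3a1, Krt5 was at -1.51, Hs6st2 at -1.39 and Pcp4 at 0.90, no longer called, nor were they without overload replicate 1 (-2.38, -2.11 and 0.79), and Krt5 (-1.95) and Hs6st2 (-1.90) also not without overload replicate 2. Cyp1b1 stayed called and was at -6.82 without overload replicate 2. The count was 186 in the fit of the Printex90 libraries alone and 268 without the 8 libraries of high Col3a1. It was 306 and 174 without non-overload replicates 1 and 2, and 158, 293 and 310 without overload replicates 1, 2 and 3.

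With G3-1, a titanium dioxide, overload changed few genes, and most of them rose. Mmp8 rose from 11.1 ± 0.317 to 19 ± 3.41 CPM (log2 0.78, SE 0.11, adjusted p = 0.000236 by edgeR's quasi-likelihood test), Pcp4, which encodes a calmodulin regulator, by 1.12, Sost by 0.97, Dlec1 by 0.91, Fcrlb by 0.76, Tspan10 by 0.67 and Mmp10, a stromelysin gene, by 0.66. Gstp1, a glutathione transferase gene, fell from 225 ± 4.09 to 183 ± 7.24 CPM (log2 -0.30, SE 0.045, adjusted p = 0.000796), Lmo4 had -0.34 and Rcan1 -0.24. Few members of the lists passed singly. Alternative activation genes rose with no member past the threshold over all genes and 1 up adjusted over the list alone (median 0.14, fry adjusted p = 0.000749, and adjusted p = 0.0136 with an estimated correlation), and heat shock genes fell with none past it over all genes and 4 down adjusted over the list alone (median -0.06, fry adjusted p = 0.00111, and adjusted p = 0.0475 with an estimated correlation). Hypoxia and glycolysis genes rose by fry with 2 up of 25, Gpi at 0.37 and P4ha1 at 0.26, and 16 adjusted over the list alone (median 0.29, fry adjusted p = 0.0161, and adjusted p = 0.077 with an estimated correlation). Neutrophil markers (fry adjusted p = 0.00434, and adjusted p = 0.0537 with an estimated correlation) and alveolar macrophage identity genes (fry adjusted p = 0.0485, and adjusted p = 0.191 with an estimated correlation) also rose, the latter with Siglec1 at 0.45 and Slc7a2 at 0.47. In all 83 genes differed, 76 higher and 7 lower. Mmp8, Pcp4 and Gstp1 kept their call whichever library was left out. Dlec1 lost it without control replicate 1 (0.78), Fcrlb without control replicate 2 (0.64), and Sost without control replicate 1 (0.96) or 2 (1.03) or overload replicate 3 (0.80), while Tspan10, Mmp10, Lmo4 and Rcan1 lost it without any of 4 or more libraries. Replicates 1 and 2 of both groups were libraries of high Col3a1, and without the 8 such libraries edgeR called 0 genes, where 1 library per group was left. The count was 1 in the fit of the G3-1 libraries alone, 32, 33 and 233 without control replicates 1, 2 and 3, and 26 without overload replicate 3. The 83 calls therefore depend on the spread taken from the libraries of all particles. DESeq2 called 209 genes, and edgeR 162 with the fibroblast marker level in the fit.

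G3-1 non-overload did not differ from its control at the threshold. EdgeR called 0 genes, with 802 at an unadjusted p under 0.05, and DESeq2 called 14. No list passed the fry test, while 3 did with the fibroblast marker level in the fit. Control held 2 libraries of high Col3a1 (31.1 and 109 CPM) and non-overload none, so this comparison is not free of that difference. Mmp8 was at 11.1 ± 0.317 CPM in control and 12 ± 1.15 CPM in non-overload. Between overload and non-overload 4 genes differed, all higher in overload: Mmp8 by 0.66, the chemerin receptor gene Cmklr1 by 0.35, Emilin2 by 0.33 and the integrin gene Itga5 by 0.23 (edgeR adjusted p = 0.00871, 0.0345, 0.00741 and 0.0345). This count was 0 in the fit of the G3-1 libraries alone, 0 without non-overload replicate 2, 2 without non-overload replicate 1 or 3, 1 without overload replicate 2 and 0 without overload replicate 3. Overload held 2 libraries of high Col3a1 and non-overload none, and with the fibroblast marker level in the fit the count was 1243, and 318 without the 8 libraries. DESeq2 called 8 genes, and edgeR 2 without the filter on low counts.

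Bayertitan, the last titanium dioxide, raised genes of hypoxia and glycolysis at both conditions. In overload Bnip3, a mitophagy gene induced by hypoxia, rose from 69 ± 9.21 to 131 ± 9.29 CPM (log2 0.92, SE 0.16, adjusted p = 0.00767 by edgeR's quasi-likelihood test), Aldoc by 1.16, Pdk1 by 0.70, the glycogen synthase gene Gys1 by 0.68, F13a1 by 1.04 and Apln from 0.643 ± 0.399 to 2.69 ± 0.609 CPM (log2 2.06). Mk1 had -0.43, Ptcd2 -0.41 and Gstp1 -0.26. Of 25 genes in the hypoxia and glycolysis list 7 rose and none fell (19 adjusted over the list alone, median 0.42, fry adjusted p = 0.00201, and adjusted p = 0.00366 with an estimated correlation), and it was the 1 list of 33 past the threshold. In all 48 genes differed, 31 higher and 17 lower. Without control replicate 1 Bnip3 was at 0.83, Pdk1 at 0.60 and Apln at 1.64, and all named genes but Gstp1 lost their call, which Gstp1 lost without control replicate 3 (-0.23) or overload replicate 1 (-0.22). Bnip3 and Pdk1 kept their call without any other library, while Aldoc, Gys1, F13a1, Apln and Ptcd2 lost it without at least 5 of the 6 and Mk1 also without overload replicate 1 (-0.35). The count was 3, 18 and 19 without control replicates 1, 2 and 3, and 9, 8 and 16 without overload replicates 1, 2 and 3. DESeq2 called 128 genes, and edgeR 86 without the 8 libraries of high Col3a1 and 75 with the replicate number as a block.

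In Bayertitan non-overload the same list rose, 8 of 25 up (19 adjusted over the list alone, median 0.35, fry adjusted p = 0.00723, and adjusted p = 0.0327 with an estimated correlation), with Aldoc at 1.07, Bnip3 at 0.84 and Pdk1 at 0.65. Stac2 rose by 0.64, while Fam71a had -0.81, Lrp8 -0.43, Mk1 -0.41 and Sdr9c7 -0.35. Altogether 49 genes passed edgeR's test, 27 higher and 22 lower. The 8 named genes lost their call without control replicate 1, where Bnip3 was at 0.75, and each lost it without at least 1 other library. The count was 1, 19 and 13 without control replicates 1, 2 and 3, and 21, 7 and 4 without non-overload replicates 1, 2 and 3. DESeq2 called 178 genes, and edgeR 97 with the fibroblast marker level in the fit, 90 without the 8 libraries, 98 with the block and 23 without the filter on low counts. Between overload and non-overload of Bayertitan edgeR called 0 genes, with 553 at an unadjusted p under 0.05, and DESeq2 called 7. Bnip3 was at 124 ± 10.6 CPM in non-overload and 131 ± 9.29 CPM in overload.

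**Figure D3:**
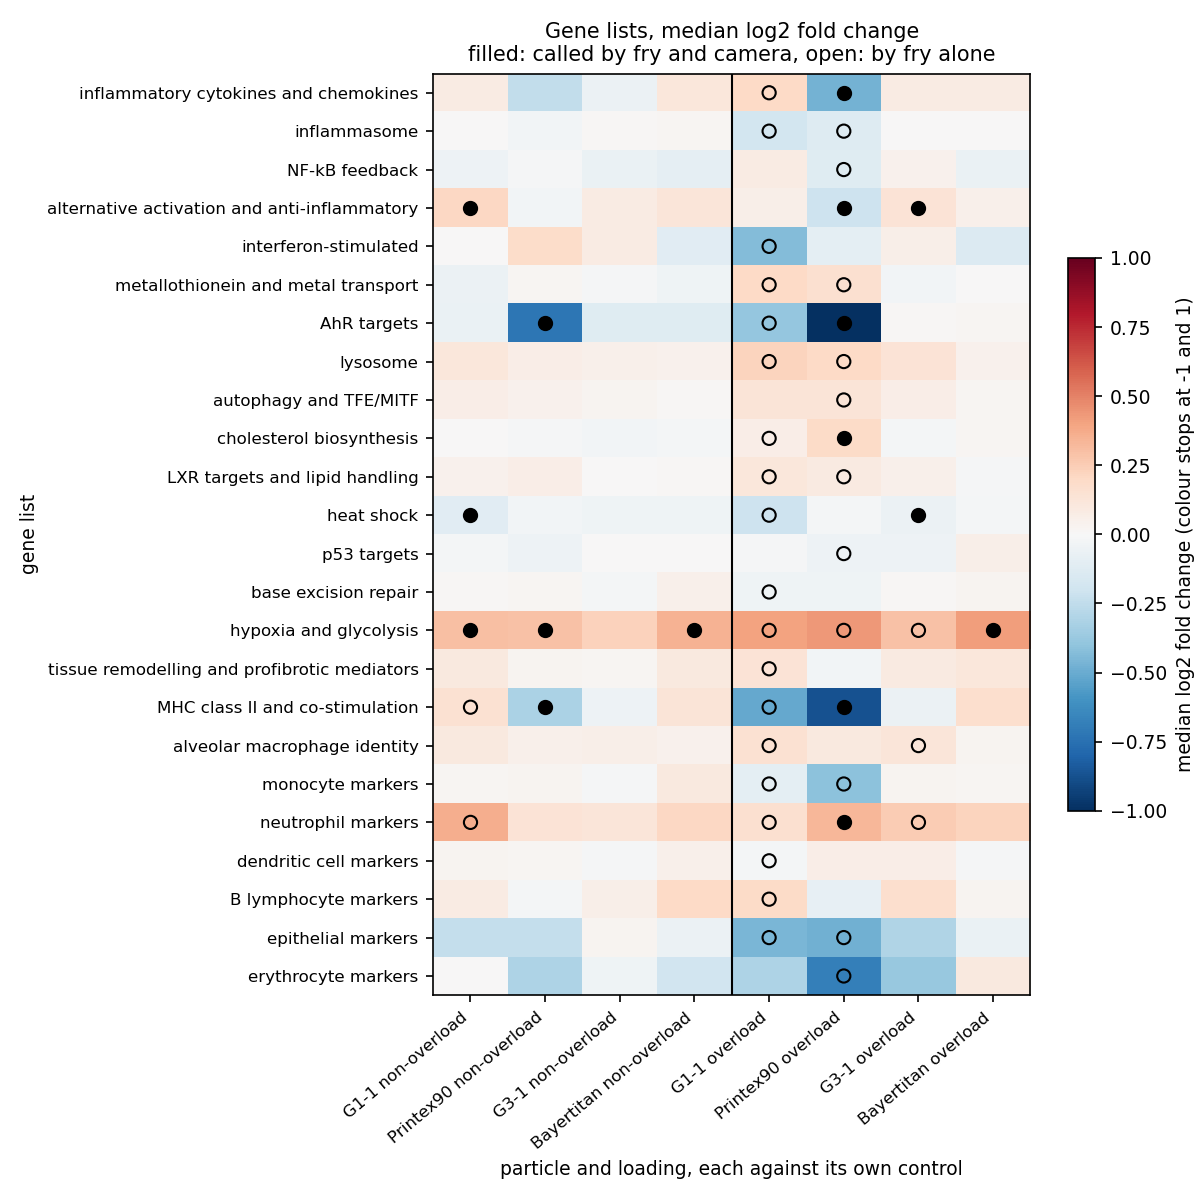
Median log2 fold change of gene lists in overload and non-overload against control, for each particle, as colour, with a filled circle for lists called by fry and with an estimated correlation and an open circle for lists called by fry alone. AhR targets had a median of -1.16 in Printex90 overload and -0.39 in G1-1 overload, and hypoxia and glycolysis genes medians from 0.29 to 0.43 in the 4 overload comparisons.

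Differences between the overload responses were tested directly, each as the change of a particle against its control minus that of another. The response to Printex90 stood apart from that to every titanium dioxide in AhR targets. Its fall of Cyp1b1 exceeded that with G1-1 by 5.00 on the log2 scale (adjusted p = 1.6e-05 by edgeR's quasi-likelihood test), and its difference was -5.06 against G3-1 (adjusted p = 6.27e-05) and -5.03 against Bayertitan (adjusted p = 6.95e-05). Without Printex90 overload replicate 2 these were 8.16, -8.22 and -8.18. For AhR targets the difference had medians of 1.39 for G1-1 minus Printex90, -1.09 for Printex90 minus G3-1 and -1.04 for Printex90 minus Bayertitan (fry adjusted p = 4.92e-08, 7.26e-09 and 6.37e-10, and adjusted p = 0.00151, 6.14e-07 and 3.06e-07 with an estimated correlation). Cytokine genes also differed, with 8 of 25 higher with G1-1 than with Printex90 (11 adjusted over the list alone, fry adjusted p = 1.32e-05, and adjusted p = 0.0226 with an estimated correlation). Heat shock genes were lower with G1-1 than with Printex90, 7 down and 2 up of 15, the same numbers adjusted over the list alone (fry adjusted p = 4.04e-06, and adjusted p = 0.0404 with an estimated correlation). MHC class II genes were lower with Printex90 than with G3-1 (median -0.82, 7 of 14 down and 9 adjusted over the list alone, fry adjusted p = 2.29e-08, and adjusted p = 9.31e-07 with an estimated correlation) and than with Bayertitan (median -1.05, 7 down and the same adjusted over the list alone, fry adjusted p = 6.98e-09, and adjusted p = 9.14e-07 with an estimated correlation).

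G1-1 minus Printex90 gave 1628 genes (648 positive, 980 negative), G1-1 minus G3-1 gave 1355 (455 and 900) and G1-1 minus Bayertitan 1790 (795 and 995). Tlr1 was lower with G1-1 than with G3-1 by a log2 difference of -2.60 and than with Bayertitan by -2.08, and Fcrl2 by -2.03 and -2.27. Printex90 minus G3-1 gave 94 genes (18 and 76) and Printex90 minus Bayertitan 173 (61 and 112), with Mmp8 higher with Printex90 by 1.10 and 1.60. MHC class II genes were lower with G1-1 than with G3-1 (median -0.44, fry adjusted p = 0.0016, and adjusted p = 0.429 with an estimated correlation) and than with Bayertitan (median -0.71, fry adjusted p = 0.000203, and adjusted p = 0.21 with an estimated correlation). Cholesterol biosynthesis was higher with Printex90 than with G3-1 (median 0.24, fry adjusted p = 7.28e-05, and adjusted p = 0.00138 with an estimated correlation) and than with Bayertitan (median 0.23, fry adjusted p = 0.000259, and adjusted p = 0.00772 with an estimated correlation). For G3-1 minus Bayertitan edgeR called 0 genes, with 565 at an unadjusted p under 0.05, DESeq2 called 7, and no list passed. Without the 8 libraries of high Col3a1, G1-1 minus G3-1 gave 787 genes and Printex90 minus G3-1 48. Printex90 minus G3-1 gave 59 in the fit of these particles alone, 177 by DESeq2 and 187 with the fibroblast marker level in the fit. Printex90 minus Bayertitan gave 277 with that level, 104, 103 and 317 without Printex90 control replicates 1, 2 and 3, 93 without Printex90 overload replicate 1, 107 and 106 without Bayertitan control replicates 2 and 3, and 97 without Bayertitan overload replicate 1.

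Across the 4 particles, 13 genes were called the same way in every overload comparison. Those that rose were Nav1, Slc7a2, Enpp3, Fmo5, Egln1, Gpi, Pld1, Dlec1, Narf, Ak4, Scd2 and P4ha1, and Gstp1 fell, all named here because of the count and after their values were seen. Independent lists of the same sizes would share 0.00164 genes upward and 8.59e-05 downward. The 4 lists are not independent, since 1 fit gave each gene 1 spread for all of them. Genes with a small spread are more easily called in every list, so such numbers do not measure chance. Egln1 and P4ha1 encode prolyl hydroxylases induced by hypoxia, and Gpi a glycolytic enzyme. Nav1 rose from 65.9 ± 0.755 to 171 ± 26.2 CPM with G1-1, from 65.7 ± 0.664 to 135 ± 3.93 with Printex90, from 65.2 ± 1.28 to 95.9 ± 8.58 with G3-1 and from 67.6 ± 1.22 to 84.6 ± 5.08 with Bayertitan. G1-1 and Printex90 shared 618 genes upward and 351 downward, where independent lists would share 149 and 154, with the same limit. The count of 13 was 0 when each particle was fitted alone, where G3-1 overload against control gave only 1 gene, so hardly any gene could be shared. The 13 genes thus depend on the spread taken from the libraries of all particles. Without the 8 libraries of high Col3a1, G3-1 control and overload kept 1 library each, so that fit cannot test a call shared by all 4. The count was 3, 7 and 4 without Bayertitan control replicates 1, 2 and 3 and 3, 4 and 6 without Bayertitan overload replicates 1, 2 and 3. It was 29 by DESeq2, 20 with the fibroblast marker level in the fit and 22 with the block.

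**Figure D4:**
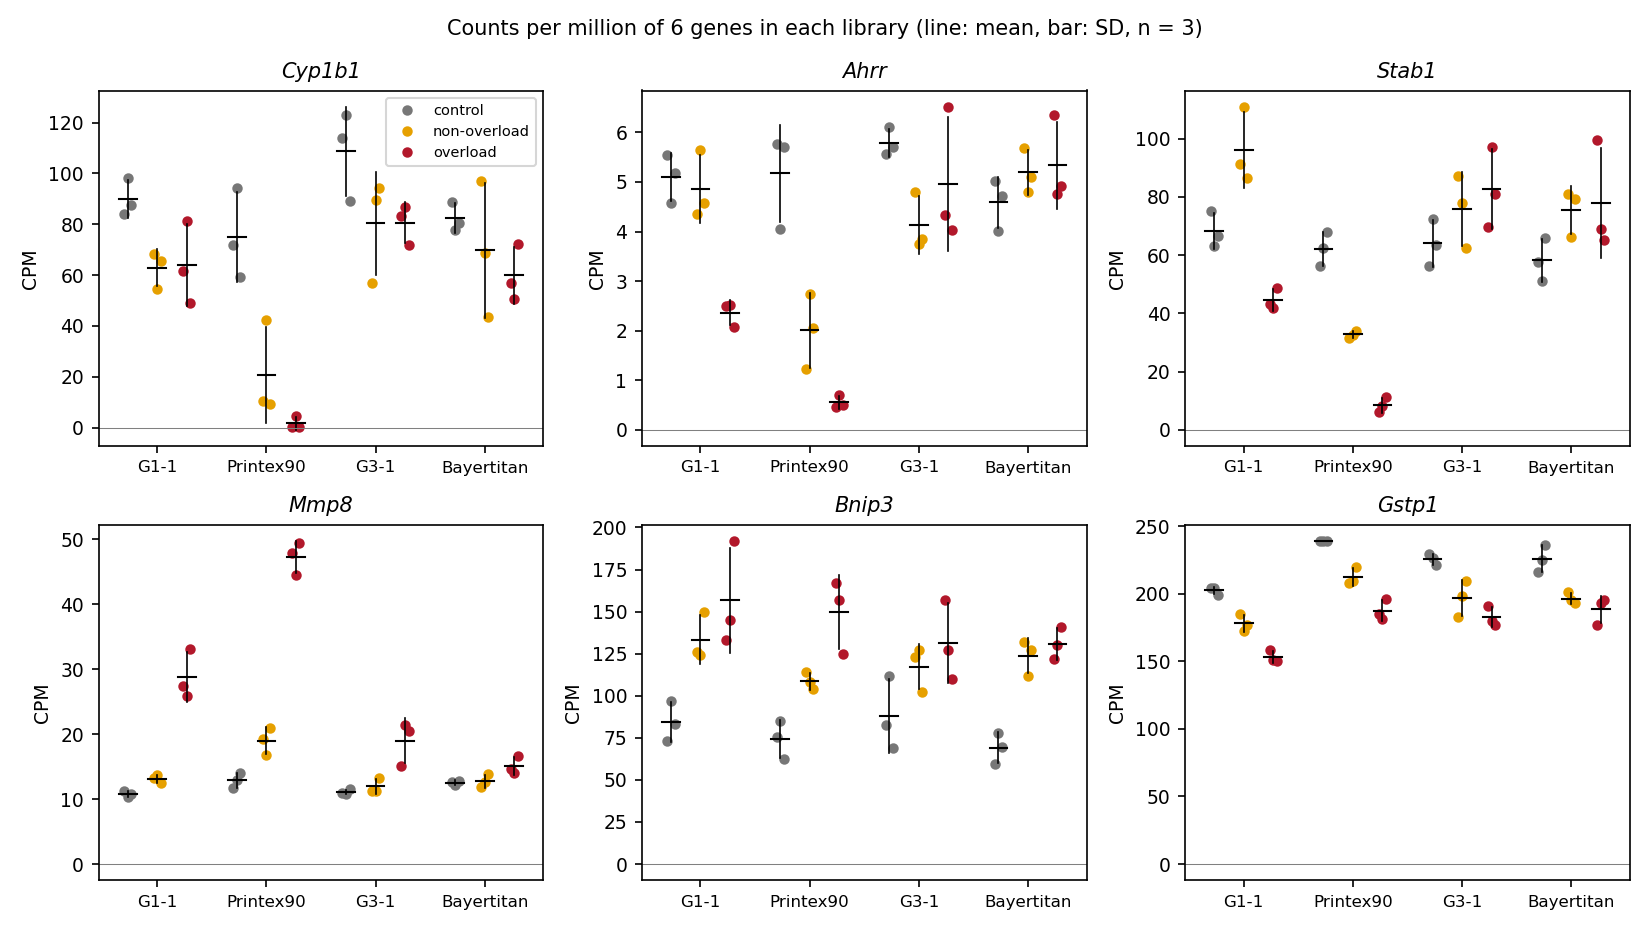
CPM of selected genes in each library by particle and condition, with 1 point per library the group mean as a line and its SD as a bar. Mmp8 reached 47.2 ± 2.49 CPM (SD, n = 3) in Printex90 overload, while Cyp1b1 was at 1.65 ± 2.52 CPM there against 75.1 ± 17.8 CPM in its control.

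The mean of the 4 overload responses differed from 0 for 4660 genes, 2100 higher and 2560 lower. Mmp8 had a mean log2 fold change of 1.09 (SE 0.054, adjusted p = 2.67e-14 by edgeR's quasi-likelihood test), Nav1 0.82 (SE 0.036, adjusted p = 1.64e-15), Sost 1.16, Dlec1 1.00, Pcp4 0.99 and Tspan10 0.92. Wnt4 had -1.09, Myrf -0.96, Cyp3a9 -0.84 and Gpr18 -0.67. Hypoxia and glycolysis genes rose, 21 of 25 (the same number adjusted over the list alone, median 0.39, fry adjusted p = 1.66e-08, and adjusted p = 0.0204 with an estimated correlation), and neutrophil markers rose with 3 of 8 up (the same number adjusted over the list alone, fry adjusted p = 5.76e-09, and adjusted p = 0.0204 with an estimated correlation). MHC class II genes fell with 10 down and 2 up of 14, the same numbers adjusted over the list alone (fry adjusted p = 1.65e-08, and adjusted p = 0.0224 with an estimated correlation), heat shock genes with 8 down and 3 up of 15, again the same adjusted over the list alone (fry adjusted p = 5.76e-09, and adjusted p = 0.0363 with an estimated correlation). AhR targets fell with 6 of 9 down (the same adjusted over the list alone, fry adjusted p = 5.76e-09, and adjusted p = 0.0204 with an estimated correlation) and Cyp1b1 at -1.72. A mean can rest on some of the particles. Neither AhR targets nor MHC class II genes passed the fry test in G3-1 or Bayertitan overload. The fall of Cyp1b1 was largest with Printex90, with differences of -5.06 against G3-1 and -5.03 against Bayertitan. Lysosomal genes rose by fry, 28 up and 1 down of 41 (adjusted p = 0.00085, and adjusted p = 0.422 with an estimated correlation), and epithelial markers fell, 10 of 16 (fry adjusted p = 0.0025, and adjusted p = 0.528 with an estimated correlation). LXR targets and dendritic cell markers had upward tests (fry adjusted p = 0.0137 and 0.0145, and adjusted p = 0.549 and adjusted p = 0.666 with an estimated correlation) and medians of 0.05 and 0.02, beside means of -0.09 and -0.05. The lists of NRF2 antioxidant genes, scavenger receptors, cell cycle, the unfolded protein response, cell death, T and NK lymphocyte markers and fibroblast and endothelial markers did not pass the fry test in any overload comparison with control or in this mean.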

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

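The splits of the differences in every form given here, and the tests of a response to the particles, of a loss of epithelial cells and of the order of AhR targets, were chosen only after the result was seen.

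Results stand here because the overload responses of a pair of particles differed in edgeR's quasi-likelihood test of the difference itself, or in fry and with an estimated correlation for lists. G1-1 minus Printex90 gave 1628 genes, with medians of 0.66 for cytokines, 0.24 for alternative activation, 1.39 for AhR targets and -0.20 for heat shock. Its named genes were Pdgfrb at 8.65, Cyp1a1 at 5.34, Cyp1b1 at 5.00, Hmgn5 at -2.36, Fcrl2 at -1.35 and Ccdc124 at -1.26. The difference in Pdgfrb, a gene of fibroblasts and pericytes, rests on replicate 2 of G1-1 overload, at 20.8 CPM, and replicate 2 of Printex90 control, at 8.93 CPM, both with high Col3a1, and it was -1.29 without the 8 libraries. G1-1 minus G3-1 gave 1355 genes (787 without the 8 libraries), with Lum at 10.80, Mmp3 at 5.94, Fzd7 at 1.28, Tlr1 at -2.60, Fcrl2 at -2.03 and Klrk1 at -1.60. Lum reached 9.79 CPM in G3-1 control replicate 2 and Mmp3 36.3 CPM in G1-1 overload replicate 2, libraries with high Col3a1, and other libraries of Lum stood at 0, so its fitted value depends on the prior count. G1-1 minus Bayertitan gave 1790 genes, with Mogs at 6.45, Epor at 1.42, Scd at 1.33, Krt15 at -2.39, Fcrl2 at -2.27 and Tlr1 at -2.08. Mogs ran from 0 to 0.5 CPM in the G1-1 controls and from 1.84 to 4.45 CPM in the Bayertitan controls, and its difference was 12 without G1-1 control replicate 3 and 12.7 without Bayertitan overload replicate 1. Lum was at 4.10 without G3-1 control replicate 2, Mmp3 at -0.33 without G1-1 overload replicate 2 and Pdgfrb at 2.87 without that library. Pdgfrb, Hmgn5, Lum, Mmp3, Fzd7, Klrk1, Mogs, Epor and Krt15 lost their call without at least 1 library, while Cyp1a1, Cyp1b1, Fcrl2, Ccdc124, Tlr1 and Scd kept theirs.

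Printex90 minus G3-1 gave 94 genes (48 without the 8 libraries, 177 by DESeq2), with medians of -0.51 for cytokines, -0.31 for alternative activation, -1.09 for AhR targets, 0.24 for cholesterol biosynthesis, -0.82 for MHC class II and -0.18 for monocyte markers. Its named genes were Mmp8 at 1.10, Mcf2l at 0.81, Scd2 at 0.53, Cyp1a1 at -5.48, Cyp1b1 at -5.06 and Ptges at -4.12. Printex90 minus Bayertitan gave 173 genes (93 without Printex90 overload replicate 1 and 317 without Printex90 control replicate 3), with medians of -0.60 for cytokines, -0.24 for alternative activation, -1.04 for AhR targets, 0.23 for cholesterol biosynthesis and -1.05 for MHC class II. Igf2bp1 had 2.09, Mmp8 1.60, Tspan10 0.96, Cyp1a1 -5.42, Cyp1b1 -5.03 and Aqp3 -4.57. Without Printex90 overload replicate 2, Cyp1a1 was at 9.21, -9.34 and -9.28 and Cyp1b1 at 8.16, -8.22 and -8.18 in G1-1 minus Printex90, Printex90 minus G3-1 and Printex90 minus Bayertitan, all still called. Mcf2l, Igf2bp1, Tspan10 and Aqp3 (-3.04 without Bayertitan overload replicate 3) lost their call without at least 1 library, and the other genes named here kept theirs.

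Libraries were exchanged between the particles within control and within overload, in fits of those particles alone, and 100 distinct splits were counted per difference, the real one included and a mirror image counted once. Such an exchange puts the differences between particles into the spread within groups, and in some splits into the difference itself, so it neither excludes chance nor argues for it in any of the 6 differences. The number of splits with as many genes, the real count and the highest other were 12, 1559 and 3458 for G1-1 minus Printex90, 13, 926 and 2866 for G1-1 minus G3-1, 4, 1679 and 2291 for G1-1 minus Bayertitan, 10, 59 and 3270 for Printex90 minus G3-1, and 9, 192 and 844 for Printex90 minus Bayertitan. For G3-1 minus Bayertitan all 100 splits gave at least the real count of 0 by edgeR (565 genes at an unadjusted p under 0.05, 7 by DESeq2), the highest 699. The 3270, 844 and 699 genes may come from differences between particles or from a structure of the samples, which these splits do not tell apart. The split with 3270 exchanged all overload libraries, G3-1 control replicate 3 and Printex90 control replicate 2. It thereby put Printex90 control replicate 2 together with G3-1 control replicates 1 and 2, all libraries of high Col3a1. A first draw of 25 such splits could repeat the real one in mirror image, and 6, 7, 1, 4, 2 and 25 reached the real count in the order above. A draw of 82 that exchanged 1 control and 1 overload library per particle gave highest others of 0, 815, 0, 0, 1 and 7, and excludes nothing for the same reason.

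The first pattern weighed is the high level of fibroblast markers in 8 libraries. A response to the particles is argued against by 3 control libraries among the 8. Of 10 further stromal genes written down before they were looked at, 2 (Fstl1 and Ddr2) were higher in each of the 8 than in any other library, which met the bound of 5 or fewer set beforehand against fibroblasts among the cultured cells. That bound was badly chosen, since 7 of the 10 genes had a median of 10 CPM or more in the other 28 libraries, a level that hides a small share of such cells, and 8 of the 10 had a higher median in the 8, Thy1 and Mfap4 being the exceptions. Fibroblasts in varying numbers therefore stay open, and a mislabelled library was not tested.

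The second pattern is the fall of AhR targets with Printex90. Loss of fibroblasts as the cause is argued against by Cyp1b1, whose log2 fold change was -5.29 without the 8 libraries and -5.49 with them. For loss of epithelial cells as a whole, the median of the epithelial markers was -0.48, far smaller than the fall of Ahrr at -3.22. This median does not decide the question, since many such markers can also be expressed by macrophages, which could hide a loss. The basal marker Krt5 at -3.20 and the club cell gene Scgb1a1 fell much further than the median, so loss of epithelial cells stays open. In 6 of 6 called targets (Cyp1a1, Cyp1b1, Ahrr, Aldh3a1, Nqo1 and Ugt1a6) the non-overload mean lay between control and overload. Lower AhR signalling with more carbon black would give this order, but so would a graded loss of epithelial cells. Krt5 had the same order, at 43.3, 21.4 and 4.73 CPM in Printex90 control, non-overload and overload. The order therefore does not tell these explanations apart. The fall of AhR targets may also be a biological response or may follow from ligands in the medium that bind to carbon black, and neither was tested.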

How the results depend on the processing

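The fibroblast level as a covariate and the fit without the 8 libraries of high Col3a1 were chosen only after the data were seen; every other alternative was planned. Counts of genes called by edgeR are given where an alternative moved them by over 1.5 times, and the cause was not tested. G1-1 overload against control stayed within that range, from 2931 to 4142 genes when 1 library was left out, as did G1-1 overload against non-overload (2549 to 3077), G1-1 minus Printex90 (1217 to 1751), G1-1 minus Bayertitan (1266 to 1870) and the mean response (3979 to 5160). DESeq2's size factors moved no count that far.

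DESeq2 called 157 genes in G1-1 non-overload against control, 58 in Printex90 non-overload against control, 209 in G3-1 overload against control, 14 in G3-1 non-overload against control, 8 in G3-1 overload against non-overload, 128 in Bayertitan overload against control, 178 in Bayertitan non-overload against control, 7 in Bayertitan overload against non-overload, 177 in Printex90 minus G3-1, 7 in G3-1 minus Bayertitan and 29 in all 4 particles. Without the filter on low counts, 2 genes were called in G3-1 overload against non-overload and 23 in Bayertitan non-overload against control. With only the libraries of the particles compared, which leaves fewer degrees of freedom, the counts were 0 in G1-1 non-overload against control, 1373, 5 and 186 in Printex90 overload and non-overload against control and overload against non-overload, 1, 1 and 0 in the same comparisons of G3-1, 59 in Printex90 minus G3-1 and 0 in all 4 particles. Bayertitan lost as many degrees of freedom and gave 55 and 36 genes in overload and non-overload against control, where the joint fit gave 48 and 49. Fewer degrees of freedom alone therefore do not account for the falls. Replicate pairs differed by a chi-square per degree of freedom of 12 to 35.4 within G3-1 control and overload, and of 3.71 to 13 within those of Bayertitan. The spread thus differs between particles, and the cause was not tested.

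With the fibroblast level as a covariate the counts were 201 in G1-1 non-overload against control, 58 in Printex90 non-overload against control, 162 and 1243 in G3-1 overload against control and against non-overload, 97 in Bayertitan non-overload against control, 187 in Printex90 minus G3-1, 277 in Printex90 minus Bayertitan and 20 in all 4 particles. Without the 8 libraries they were 11 in Printex90 non-overload against control, 268 in Printex90 overload against non-overload, 0 and 318 in G3-1 overload against control and against non-overload (1 library is left in 2 of the groups and is taken to vary like the other groups), 86 and 90 in Bayertitan overload and non-overload against control, 787 in G1-1 minus G3-1, 48 in Printex90 minus G3-1 and 0 in all 4 particles.

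Outside Printex90 non-overload against control, in no comparison within a particle did all 3 pairs of libraries with the same number have deviations correlated over 0.1. Over all comparisons 9 of 36 pairs did (range -0.25 to 0.54), and 20 of 36 libraries correlated best with their own number, a hint from the data and not the design. G3-1 overload against control came close, at 0.22, 0.099 and 0.54. In both comparisons libraries of high Col3a1 shared a number, which can itself make deviations correlate, so these values do not establish pairs. With the replicate block Printex90 non-overload against control gave 35 genes, and besides Mcf2l and the cytokine list no call of a named gene or list changed there. The counts with the block were 1 in G3-1 non-overload against control, 75 and 98 in Bayertitan overload and non-overload against control and 22 in all 4 particles, and lists called were 8 in G3-1 overload and 2 in Bayertitan overload; the other counts moved by less than 1.5 times.

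Leaving out 1 library at a time, the counts were 3 to 36 in G1-1 non-overload against control (17, 15 and 15 without controls 1, 2 and 3, and 25, 3 and 36 without non-overload replicates 1, 2 and 3). They were 997 to 2861 in Printex90 overload against control (1081 and 1168 without controls 1 and 2, 997 without overload replicate 1), 9 to 27 in Printex90 non-overload against control (12 and 9 without controls 1 and 2, and 10, 19 and 14 without non-overload replicates 1, 2 and 3) and 158 to 614 in Printex90 overload against non-overload (306 and 174 without non-overload replicates 1 and 2, and 158, 293 and 310 without overload replicates 1, 2 and 3). In G3-1 they were 26 to 233 for overload against control (32, 33 and 233 without controls 1, 2 and 3, 26 without overload replicate 3), 0 for non-overload against control by edgeR (802 genes at an unadjusted p under 0.05 with all libraries), and 0 to 3 for overload against non-overload (0 without non-overload replicate 2 or overload replicate 3, 2 without non-overload replicate 1 or 3, 1 without overload replicate 2). In Bayertitan they were 3 to 19 for overload against control (3, 18 and 19 without controls 1, 2 and 3, and 9, 8 and 16 without overload replicates 1, 2 and 3), 1 to 21 for non-overload against control (1, 19 and 13 without controls 1, 2 and 3, and 21, 7 and 4 without non-overload replicates 1, 2 and 3), and 0 for overload against non-overload by edgeR (553 at an unadjusted p under 0.05). Printex90 minus G3-1 gave 71 to 134, Printex90 minus Bayertitan 93 (without Printex90 overload replicate 1) to 317 (without Printex90 control replicate 3), G1-1 minus G3-1 1031 to 1418, G3-1 minus Bayertitan 0 to 1 (without G3-1 overload replicate 3), and all 4 particles 3 (without Bayertitan control replicate 1 or overload replicate 1) to 14.

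Lists past the threshold numbered 19 in G1-1 overload (0 with camera, 12 without control replicate 2, up to 21), 5 in G1-1 non-overload (10 with the covariate, 3 with camera) and 11 in G1-1 overload against non-overload (1 with camera). In Printex90 there were 17 in overload (6 with camera, 11 without control replicate 1, 10 without overload replicate 1, up to 16), 3 in non-overload (5 with the covariate) and 8 in overload against non-overload (13 with the covariate, 5 with camera). In G3-1 there were 5 in overload (8 with the covariate, 2 without the 8 libraries, 2 with camera, 4 to 10 with 1 library left out, 10 without control replicate 3 and 8 without overload replicate 2), 0 in non-overload (3 with the covariate) and 0 in overload against non-overload (12 with the covariate, 4 without the 8 libraries). In Bayertitan there was 1 in overload and 1 in non-overload (2 with the covariate and 2 without the 8 libraries in each), and in the mean response 20 (5 with camera).

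Signs turned for 5 genes: Pdgfrb in G1-1 minus Printex90 (-1.29 without the 8 libraries), Lck in the mean response (-0.00382 without them), Mmp3 in G1-1 minus G3-1 (-0.327 without G1-1 overload replicate 2, up to 9.17), and, in the mean response with 1 library left out, Jchain (-0.0281 without Printex90 overload replicate 1, up to 0.162) and Hdc (-0.0569 without Printex90 overload replicate 3, -0.0157 without G3-1 overload replicate 2, -0.000855 without G3-1 control replicate 3, up to 0.194). Of the other values of named genes, 270 kept their side of the threshold under DESeq2, 277 with its size factors, where 1 lost it, and 275 with the covariate, where 3 lost it; 16 lost it without the filter, 13 with the block, 40 without the 8 libraries and 57 with only the libraries compared. The 57 stand beside 78 values that kept their side with only the libraries compared, where the mean response was not fitted. Over the fits that left out 1 library, 4045 values kept their side, 346 lost their call and 8 gained one. Under DESeq2, values without an adjusted p were left out. Depth limits genes near the floor. Trappc2b is not such a case, with a mean of over 1 CPM in Printex90 control. It was at 0 in the 3 Printex90 overload libraries, which had 29.3 to 39.8 M counts, and the cause was not tested.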

Other observations

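The split counts of the comparisons within a particle and of the mean response, and the choice of the lists of lysine- and glutamate-rich proteins, came only after the result was seen, while the bounds on those lists' medians were written before the medians were computed.

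Ribosomal protein genes, which were in none of the fixed lists, fell with G1-1 overload, and the difference from the other particles was not tested. Of 66 genes 42 fell and 1 rose with G1-1 (median log2 fold change -0.37, quartiles -0.49 and -0.17, fry adjusted p = 0.000348, and adjusted p = 0.416 with an estimated correlation). The medians were -0.06 with Printex90, -0.03 with G3-1 and 0.01 with Bayertitan, with fry adjusted p = 0.591, 0.761 and 0.807, and no gene called by edgeR. Genes of ribosome biogenesis outside the lysine- and glutamate-rich proteins had a median of -0.09 with G3-1 (fry adjusted p = 0.00784, and adjusted p = 0.141 with an estimated correlation) and of -0.08 with Printex90 (fry adjusted p = 0.0145, and adjusted p = 0.434 with an estimated correlation).

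The third pattern weighed is the fall in G1-1 overload of lists of genes for proteins rich in lysine and glutamate, whose codons are purine-rich, among them Hsp90b1 at -0.77, Ccdc124 at -1.17 and Hsp90ab1 at -0.51. The lists were written from textbook knowledge without sequences, the share of such genes among all lower genes was not counted, and 30 of 34 nuclear ones fell (median -0.41, fry adjusted p = 4.3e-10, and adjusted p = 0.00773 with an estimated correlation) and 21 of 30 cytoplasmic ones (1 rose, median -0.26, fry adjusted p = 2.59e-12, and adjusted p = 0.000688 with an estimated correlation). The first median passed the bound of -0.3 set for a loss of purine-rich RNA in the libraries. The lists were chosen after the result of this same comparison was seen, so their fall and its p-values are no independent test. Without sequences the purine content was not measured either, so this pass decides nothing. The second median lay between the bounds of -0.3 and -0.1 and also decides nothing. Lower ribosome biogenesis as a cell response had a median of -0.13 in 33 other genes of that process (12 fell, 1 rose, fry adjusted p = 0.000704, and adjusted p = 0.434 with an estimated correlation), also between the bounds. A technical and a biological origin thus both stay open, and the nuclear list had medians of -0.07, -0.07 and -0.01 with Printex90, G3-1 and Bayertitan.

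Within a particle, 3 libraries against 3 make 10 splits, too few for a share under 0.05, and these fits held 1 particle's libraries alone. For overload against control the real and highest other counts were 3456 and 2 with G1-1, 1373 and 1 with Printex90, 1 and 1982 with G3-1, and 55 and 0 with Bayertitan. With G3-1 2 of 10 splits reached the real count, and the 1982 genes came from controls 1 and 2 with overload replicate 1, all with high Col3a1, against the rest, which points to a structure of the samples. High Col3a1 alone does not set that split apart, since overload replicate 2 (31.4 CPM) was among the rest. For non-overload against control they were 0 and 1 with G1-1 (10 of 10 splits), 5 and 488 with Printex90 (3 of 10), 1 and 0 with G3-1, and 36 and 1 with Bayertitan. The 488 genes came from Printex90 controls 1 and 2 with non-overload replicate 2, a split that puts both libraries of high Col3a1 on 1 side. With the replicate numbers read as pairs, the 3 other splits that part all 3 pairs gave 0 genes, while those with 488 and 7 genes part 1 pair. For overload against non-overload they were 2674 and 0 with G1-1, 186 and 1 with Printex90, 0 and 0 with G3-1, and 0 and 2 with Bayertitan, the last 2 reached by 10 of 10 splits. For the mean response 51 splits with the condition exchanged within each particle gave 4660 genes in the real split, 1 of 51, and 1890 in the highest other. That is the smallest share 51 splits can give. It is under 0.05 and argues against chance without any overload effect there. For the genes called in all 4 particles the counts were 13 in the real split, again 1 of 51, and 0 in every other split. That floor tells nothing about how many genes particles with unrelated responses would share, so it excludes nothing.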
